A study of Mus musculus with 4 samples.

How the data were processed

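RNA was taken from 4 cultures of cells labelled hepatocyte-like, each grown separately from the mouse embryonic stem cell line E14TG2a with an advanced hepatic-inducing cocktail (A-HIC), per the labels. E14TG2a is a male line that lacks a working Hprt1 gene. Polyadenylated RNA was made into libraries that keep no strand information and was sequenced from both ends on an Illumina instrument, per the labels' protocols. The 4 libraries form a single group and are called libraries 1 to 4 after the replicate numbers in the labels. The series asked about hepatic identity and developmental maturity, and the submitters set these libraries beside published hepatocyte and AML12 data, which are not analysed here.

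The deposited values are raw counts per gene, whole numbers without normalization. STAR and featureCounts, with the genome build GRCm39 (mm39), are named in the submitters' processing notes. Their versions, the annotation release and the counting options are not given in the sources used here. The deposited counts carry 3 features that affect the measurements. Even numbers made up 60.0% to 62.6% of the gene counts between 1 and 8, a pattern that arises when both ends of a read pair are counted, so a count may stand for less than 1 fragment. All 37 rows of the mitochondrial genome held 0 counts in every library, so that genome was not measured. How reads with several alignments were treated is not given, so genes of families with near-identical copies (Mup, Ugt2b, Cyp3a, Serpina1, Saa, Gapdh) have uncertain levels. Reads from genes that overlap on opposite strands cannot be told apart in these libraries.

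Libraries 1 to 4 held 37.8, 40.2, 29.5 and 40.1 M counts. Each library table held 78028 rows, of which 39251 had a count in at least 1 library. Gene lengths (union of exons) and gene types came from the GENCODE M21 annotation, which is built on GRCm38 and not on the submitters' build, so no coordinates are given. In all, 48850 rows were matched to it, 48151 by symbol, 51 by gene ID and 648 by an older or newer symbol, and 19970 of them were protein-coding. The matched rows held 98.9% to 99.1% of the counts. Transcript levels scaled for gene length and library size (TPM) were computed from the deposited counts and these lengths, and levels scaled for library size alone (CPM) from the deposited counts alone. Levels were averaged on the scale log2(TPM + 0.1), which understates ratios of genes with low values. A gene was called expressed at 1 TPM or more in all 4 libraries, and not detected where every library had 3 counts or fewer. Those 3 counts correspond to 0.0747 to 0.102 CPM. A count of 0 allows up to 3 fragments, which are 6 counts if both ends were counted (0.149 to 0.203 CPM), and this limit and the intervals cover counting error only.

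Gene lists, gene pairs, tests and alternatives were fixed before the data were examined. The 39 lists cover hepatocyte functions, fetal and mature hepatocyte genes, liver zonation, 14 other lineages, cell states and a check of line and sex. One list member without a length, Ahsp, was left out of TPM values. Each list's median was placed among the medians of 10000 random lists of the same size drawn from protein-coding genes, with a two-sided p and Benjamini-Hochberg adjustment over lists. The smallest unadjusted p this test can give is 0.00020. Pairs of lists were compared by permuting gene labels between them 100000 times, two-sided, with adjustment over the 14 lineage lists where these were compared with secreted hepatocyte proteins. These tests describe where genes stand in these libraries, since genes are not independent replicates. For 19 pairs of an adult liver gene and a related partner, the log2 ratio per library was tested against 0 with limma (3.58.1), adjusted over pairs. Its error is the spread between cultures, drawn by limma toward the spread common to the 19 pairs. The spread between cultures was estimated as edgeR's (4.0.16) common biological coefficient of variation, with TMM factors and filterByExpr. Each library was compared with the other 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and by the Wald test of DESeq2 (1.42.0) as an alternative. In that comparison the lone library is assumed to vary like the others. The variability of a list was the median over its members (mean CPM of 1 or more, lists with 5 or more such members) of the SD of log2(CPM + 1), set against 10000 lists matched on deciles of mean expression, one-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

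The genes named are the 20 protein-coding genes with the highest mean TPM, the highest and lowest members of each list, every pair, the 10 genes with the largest edgeR dispersion at a mean of 10 CPM or more, and the line and sex check. From these the text gives examples, and other genes are marked as chosen after their values were seen. Alternatives were CPM in place of TPM, other thresholds and pseudocounts, another background, means in place of medians, members in no other list, DESeq2 size factors, no filter on low counts, another prior for the pairs, and leaving out each library. Halved counts were added after the data were examined. The tests were run on simulated data. With the observed spread over 17398 genes, the comparison of 1 library with 3 recovered 80 of 100 changes of 4-fold and 92 of 100 of 16-fold, with 13 false calls. The pair test recovered 10 of 10 shifted pairs with 0 false calls among 10 others. The random-list test called 0 of 50 unshifted and 10 of 10 shifted lists, and the comparison of 2 lists called 7 of 100 unshifted and 100 of 100 shifted pairs of lists. The simulated pairs and the simulated 2 lists spread less than many real ones, so their rates do not give the power of the real tests. For 1 library against 3, the simulated libraries were drawn independently, whereas the real ones pair off.

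No 2 libraries were copies of each other. Over 12646 expressed protein-coding genes, the chi-square per gene between libraries, on halved counts, ran from 7.84 to 59.4, where counting noise alone gives about 1.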

Results

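The data are 4 libraries labelled hepatocyte-like cells, made from separate A-HIC cultures of the mouse embryonic stem cell line E14TG2a. At 1 TPM or more in all 4 libraries, 14795 genes were expressed, 12646 of them protein-coding. The most abundant protein-coding transcripts were Eef1a1, a translation elongation factor, at 15235 ± 586 TPM (SD, n = 4) and Hsp90ab1, a chaperone, at 8534 ± 407 TPM. Among the 20 most abundant were also Dppa5a, a marker of pluripotent cells, at 2746 ± 987 TPM, and Sparc, a matrix protein made by parietal endoderm, at 2031 ± 938 TPM. No gene specific to the liver was among them. The Y-linked genes Eif2s3y, Ddx3y and Uty stood at 120 ± 8.59, 52.5 ± 2.86 and 9.51 ± 0.977 TPM, while Kdm5d stood at 0.119 ± 0.0645 TPM and Xist at 0.532 ± 0.172 TPM. Hprt1, which is defective in this line, had 33, 10, 26 and 16 counts in libraries 1 to 4. As a list, these 6 genes did not differ from random lists (permutation, adjusted p = 0.841). The list joins Y-linked genes with Xist and the defective Hprt1, so its place does not bear on line or sex.

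The first question of the series was hepatic identity. Secreted hepatocyte proteins were scarce: 6 of the 20 listed genes were expressed, and together the 20 took 0.00467% ± 0.00122 (SD, n = 4) of all counts, or 0.00996% of summed TPM. Rbp4, the plasma carrier of retinol, was the highest at 45.2 ± 21.2 TPM. Trf, transferrin, stood at 10.1 ± 1.84 TPM, and Ttr, which carries thyroid hormone, at 4.07, 30.8, 5.99 and 16.5 TPM in libraries 1 to 4. Alb, the major plasma protein of the adult liver, had 11, 171, 0 and 12 counts in libraries 1 to 4, a mean of 2.03 ± 3.44 TPM. The 0 in library 3 allows up to 0.203 CPM if both ends were counted. Serpina1b, Serpina1a and Apoc3 had the lowest means, at 0.0827, 0.0671 and 0.0485 TPM. The list's median lay at the 2.86th percentile of random lists, which did not pass the test (permutation over genes, adjusted p = 0.102). With the background restricted to genes with 10 or more counts, with list means, or without library 2, the list was below random lists (adjusted p = 0.00117, 0.0230 and 0.0487). The count filter was applied to the background and not to the list, which favours a place below.

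**Figure D1:**
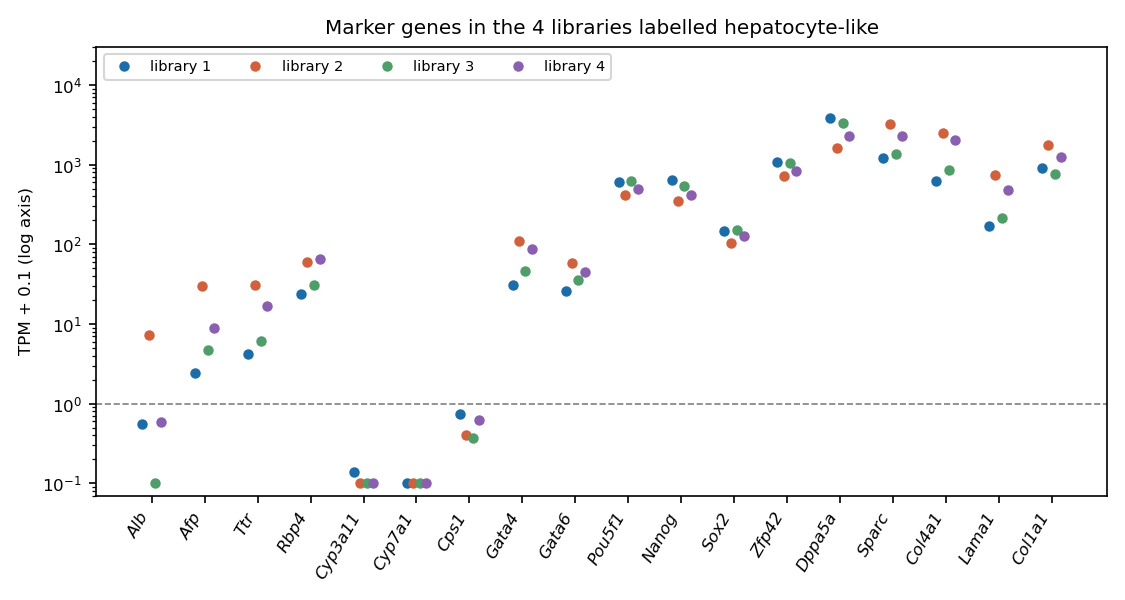
TPM + 0.1 on a log axis for marker genes named in the text, in each of the 4 libraries, with a dashed line at 1 TPM. Pou5f1 lies between 419 and 631 TPM in the 4 libraries, and Alb between 0 and 7.18 TPM.

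Hepatocyte functions differed in the share of their genes that was expressed. Of the 197 genes in the hepatocyte and mature lists together, 77 were expressed and 45 were not detected. Lipid and cholesterol metabolism stood above random lists, with 17 of 20 genes expressed (permutation, adjusted p = 0.00260). Among them were the sterol synthesis genes Hmgcs1 at 251 ± 11.4 TPM and Sqle at 134 ± 4.94 TPM, whereas Fabp1, the liver fatty acid carrier, had 0 counts in all 4 libraries. Phase I drug metabolism lay below random lists, with 3 of 23 genes expressed and 12 not detected (adjusted p = 0.00142). Por, the reductase that serves the cytochromes P450, reached 113 ± 8.90 TPM, while Cyp2j5, Cyp3a41a and Cyp4a14 had 0 counts. Coagulation and complement also lay below, with 4 of 24 expressed (adjusted p = 0.0219). C1s1 and C3 were its highest members at 13.2 ± 3.16 and 10.1 ± 4.37 TPM, and F9 had 0 counts.

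The other hepatocyte lists did not differ from random lists. Of the urea cycle genes, 5 of 8 were expressed (permutation, adjusted p = 0.855). Ass1 stood at 502 ± 73.4 TPM, while Cps1, which starts the cycle, stood at 0.434 ± 0.177 TPM and Otc at 0.0232 ± 0.0464 TPM. Hepatic transcription factors had 15 of 24 members expressed (adjusted p = 0.578), led by Tbx3 at 97.6 ± 26.1 TPM and by Gata4 and Gata6, which are also endoderm regulators, at 68.8 ± 36.9 and 41.0 ± 13.4 TPM. Nr1i3 and Onecut1 were lowest, at 0.0218 ± 0.0252 and 0.238 ± 0.221 TPM. In gluconeogenesis and glycogen, 5 of 12 were expressed (adjusted p = 0.280), with Pcx at 34.0 ± 3.00 TPM and G6pc1 at 0 counts. In bile acid synthesis and transport, 4 of 16 were expressed (adjusted p = 0.0593), with Amacr at 13.1 ± 1.22 TPM and Cyp7a1, the rate-limiting enzyme, at 0 counts. Phase II conjugation had 9 of 20 expressed (adjusted p = 0.313), with Gsta4 at 681 ± 84.6 TPM, and acute phase genes 7 of 16 (adjusted p = 0.102), with Socs3 at 64.0 ± 5.61 TPM. Among zonation genes, 3 of 10 periportal genes (adjusted p = 0.211) and 4 of 12 pericentral genes (adjusted p = 0.0593) were expressed. Glul, the pericentral glutamine synthetase, stood at 320 ± 85.6 TPM and Cyp2e1 at 0 counts. With the background restricted to genes with 10 or more counts, all of these lists except the urea cycle were below random lists. The lists themselves kept their members with fewer counts, so this filter favours a place below. Bile acid genes were also below with list means and without library 3 (adjusted p = 0.00229 and 0.0406), acute phase genes with CPM (0.0239) and pericentral genes without library 3 (0.0445).

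Genes of other lineages were then compared with the secreted hepatocyte proteins. All 23 pluripotency genes were above 10 TPM in every library, with the list median above that of the secreted proteins by 7.72 on the log2 scale (permutation, adjusted p = 0.00014). Pou5f1 and Nanog, core pluripotency factors chosen after their values were seen, stood at 539 ± 99.1 and 488 ± 133 TPM, Zfp42 at 924 ± 173 TPM and Cripto at 562 ± 133 TPM. The lowest member, Prdm14, was at 18.6 ± 5.50 TPM. These values go against the label, so the direction of every comparison given here belongs to the libraries labelled hepatocyte-like. Parietal endoderm genes, 13 of 14 of them expressed, lay 8.55 above the secreted proteins (adjusted p = 0.00014). Beside Sparc, this list was led by the basement membrane genes Col4a1 at 1501 ± 905 TPM and Col4a2 at 985 ± 558 TPM, and Tfpi2 was lowest at 0.284 ± 0.146 TPM.

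Fibroblast and stellate genes lay 6.80 above the secreted proteins (permutation, adjusted p = 0.000233), with 19 of 22 expressed and Col1a1 at 1172 ± 446 TPM and Vim at 501 ± 58.4 TPM. Visceral endoderm genes lay 4.58 above (adjusted p = 0.0157), with 13 of 14 expressed, among them Slc2a3 at 728 ± 53.6 TPM and Rhox5 at 207 ± 45.3 TPM. Cholangiocyte genes lay 3.89 above (adjusted p = 0.0447), with 14 of 17 expressed and Spp1 at 994 ± 293 TPM. This call ended with members in no other list, without library 3 and without library 4 (adjusted p = 0.0560, 0.0772 and 0.0578). Random lists of the sizes of the visceral endoderm and cholangiocyte lists had medians of 2.83 and 2.87 on the log2 scale. The secreted proteins stood at -0.60, so such random lists also lay above them. Erythroid genes, with 2 of 15 expressed and Epor the highest at 4.71 ± 0.661 TPM, were the only list below, by a difference of -2.28 (adjusted p = 0.0311). That call ended with CPM, with a pseudocount of 1, without library 2 and without library 4 (adjusted p = 0.0868, 0.0873, 0.360 and 0.0712).

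The remaining lineage lists did not differ from the secreted proteins. Trophoblast genes lay 3.20 above (permutation, adjusted p = 0.0898, and 0.0481 with list means), with Krt8 at 534 ± 92.4 TPM. Endothelial, macrophage and leukocyte, and pancreas, lung and stomach genes differed by 1.99, 1.76 and -1.23 (each adjusted p = 0.240). Pecam1, Cd68 and Gkn1 led these lists at 45.3 ± 10.5, 71.8 ± 11.7 and 31.3 ± 23.0 TPM. Primitive streak and definitive endoderm genes differed by 1.13 (adjusted p = 0.479), with Trh at 52.5 ± 14.2 TPM and Sox17 at 19.7 ± 11.3 TPM. Neural, cardiac muscle and intestine genes differed by 1.06, 0.99 and -0.73 (adjusted p = 0.530, 0.548 and 0.670). Tubb3, a neuronal tubulin, stood at 106 ± 11.4 TPM, Tnni3, a cardiac troponin, at 10.1 ± 3.83 TPM and Slc15a1 at 7.53 ± 3.91 TPM. Against random lists, pluripotency, parietal endoderm and fibroblast genes were above (each adjusted p = 0.00078), while the erythroid list (adjusted p = 0.00468) and the pancreas, lung and stomach list (adjusted p = 0.0427) were below. The last of these calls ended without library 1 (adjusted p = 0.0581). Visceral endoderm, cholangiocyte, trophoblast, endothelial and macrophage genes did not differ from random lists (adjusted p = 0.512, 0.841, 0.855, 0.530 and 0.486), nor did primitive streak, neural, cardiac and intestine genes (adjusted p = 0.350, 0.278, 0.329 and 0.0613). Intestine genes were below with CPM, with list means and without library 2 (adjusted p = 0.0406, 0.00303 and 0.0303), and cardiac genes with list means (0.0376). With the background of genes with 10 or more counts, intestine, primitive streak, neural, cardiac, endothelial and macrophage genes were below (0.000459, 0.0164, 0.00576, 0.0130, 0.0400 and 0.0264). Here too the lists were not filtered, which favours a place below.

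**Figure D2:**
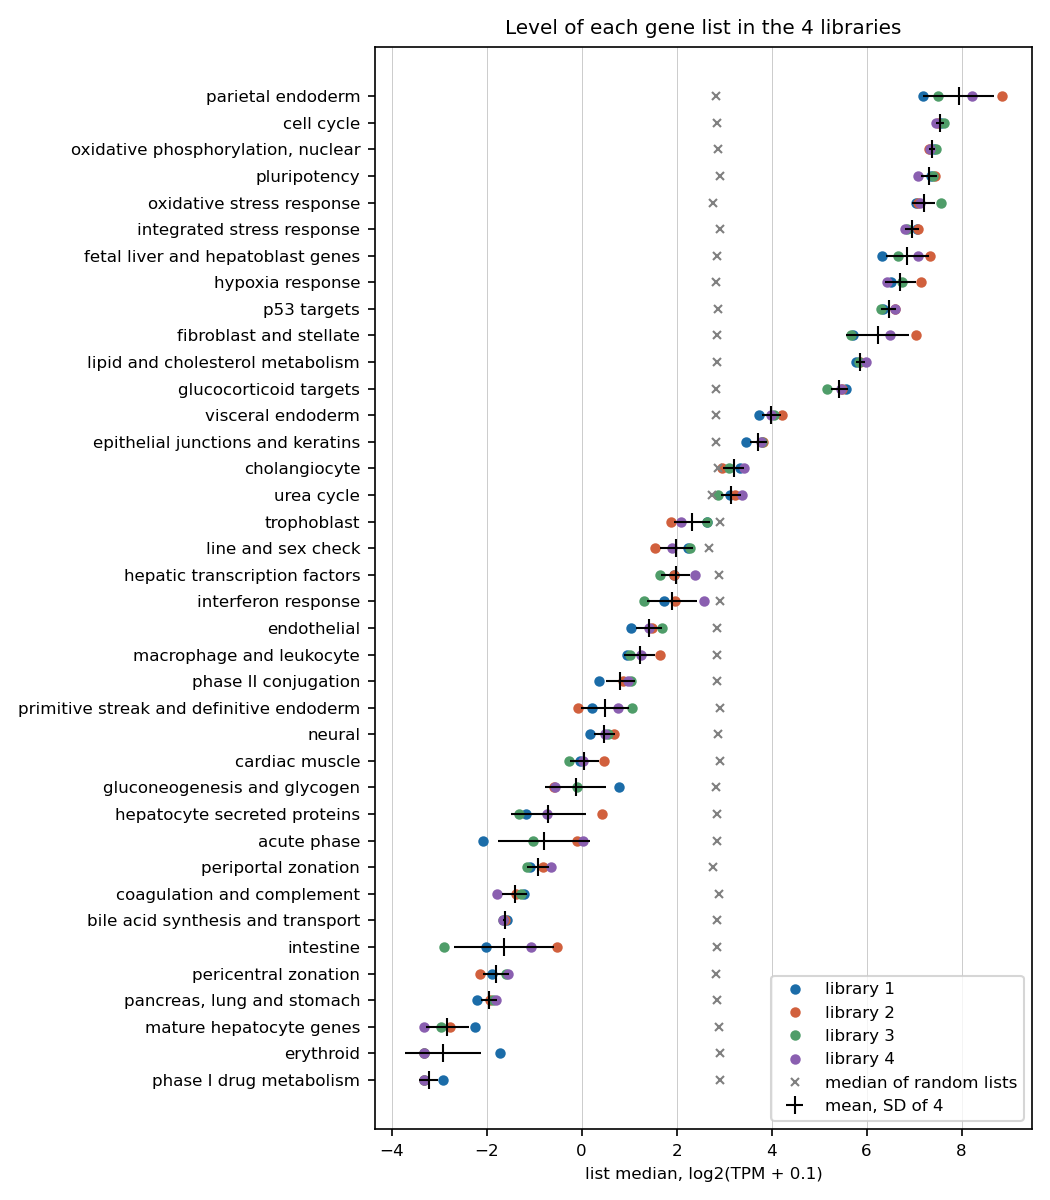
Median log2(TPM + 0.1) of each gene list in each library (points), the mean with SD over the 4 libraries (black) and the median of random lists of the same size (grey crosses). Parietal endoderm is at 7.94 and pluripotency at 7.31, and mature hepatocyte genes are at -2.83.

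The second question was developmental maturity. All 20 fetal liver and hepatoblast genes were expressed, while 3 of 30 mature hepatocyte genes were expressed and 13 were not detected. Scd2 stood at 946 ± 169 TPM, Hmga2 at 510 ± 128 TPM and Mdk at 367 ± 34.4 TPM. Afp, the fetal counterpart of albumin, stood at 11.5 ± 12.6 TPM with 30.0 TPM in library 2 and 2.35 to 8.88 TPM in the other 3. Gnmt, Arg1 and Gulo were the expressed mature genes, at 5.70 ± 3.07, 3.05 ± 0.988 and 2.35 ± 1.11 TPM, and Mup3 and Mup20 had 0 counts. The mature list median was lower than the fetal one by a log2 difference of -9.79 (permutation, p = 1.0e-05, the smallest these permutations can give). Per library the difference was -8.58, -10.11, -9.64 and -10.41. Some fetal list members, such as Lin28b and Hmga2, are also expressed by embryonic stem cells, so the list is not specific to the liver.

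Within pairs of related genes, the adult liver member was lower in 15 of 19 pairs, higher in 3 and not different in 1 (limma, adjusted over pairs). Alb was lower than Afp by a log2 ratio of -3.42 ± 1.67 (SD, n = 4), in 4 of 4 libraries (limma, adjusted p = 0.000151). This ratio had the largest SD of the 19 pairs, and the error of its test was drawn toward the smaller spread of the others. Its value in library 3 (-5.56) rests on 0 Alb counts and so on the pseudocount. Slc2a2, the hepatocyte glucose transporter, was lower than Slc2a1 (-11.53 ± 0.45), Mat1a than Mat2a (-10.94 ± 0.58), Pklr than Pkm (-9.08 ± 0.35) and Gys2 than Gys1 (-8.82 ± 0.53). Slc2a2 and Gys2 were at 3 counts or fewer in every library and Mat1a at 4 or fewer, so the size and order of these ratios depend on the pseudocount. Ratios between -1.37 and -3.29 were found for Acacb, Gls2, Scd1, Fbp1, Cebpa and Pygl against their partners. The adult member was higher for Krt18 over Krt19 (2.77 ± 0.39), Slc25a13 over Slc25a12 (1.67 ± 0.17) and Cdh1 over Cdh2 (1.62 ± 0.52), genes that other epithelia and stem cells also express. Cyp3a11 and Cyp3a16 were both near 0, with means of 0.00949 and 0.0554 TPM (limma, adjusted p = 0.402).

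**Figure D3:**
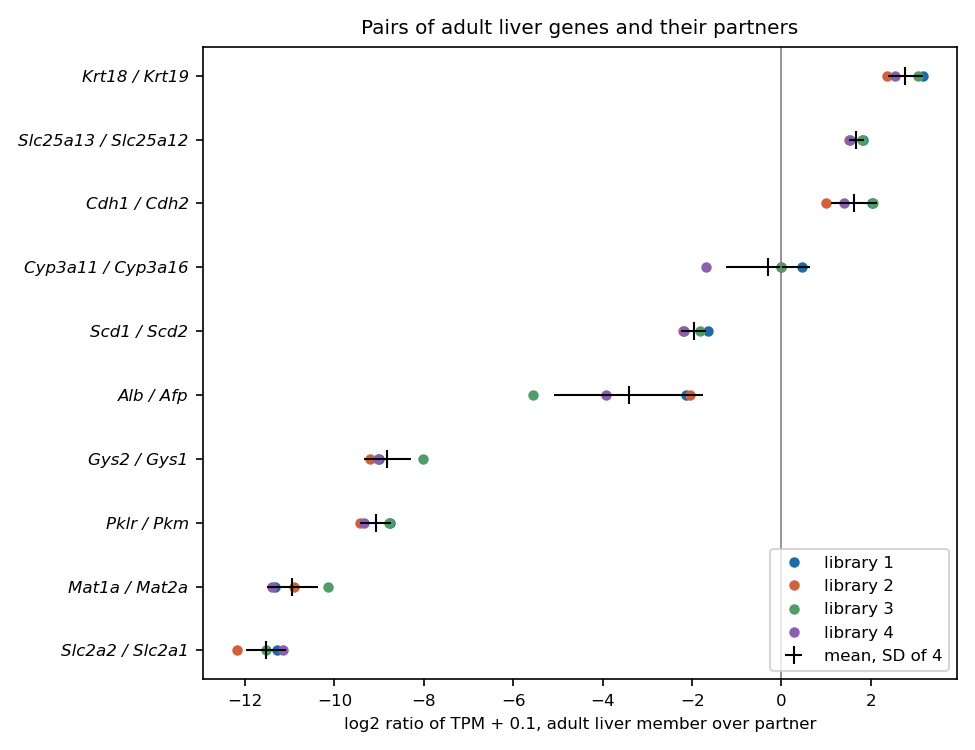
Log2 ratio of TPM + 0.1 of the adult liver gene to its partner in each library (points), with the mean and SD over 4 libraries (black), for pairs with both genes named in the text. The ratio is above 0 in all 4 libraries for Krt18, Slc25a13 and Cdh1.

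Genes of cell cycle, stress and other cell states were placed among random lists. Random lists include genes that are not expressed, and the series has no baseline group. A place above them therefore gives a level and does not show that a response was switched on. All 20 cell cycle genes were expressed, with Cdc20 at 437 ± 48.5 TPM and Mki67 (chosen after its values were seen) at 79.4 ± 4.98 TPM, and the list was above random lists (permutation, adjusted p = 0.00078). The integrated stress response, hypoxia response, oxidative stress response and nuclear oxidative phosphorylation lists had the same adjusted p. Hspa5, an endoplasmic reticulum chaperone, stood at 968 ± 169 TPM, Pgk1 at 1684 ± 152 TPM, Sqstm1 at 459 ± 12.8 TPM and Atp5f1a at 1249.7 ± 19.8 TPM. Targets of p53 were above random lists too (adjusted p = 0.00279), with Ccng1 at 933 ± 186 TPM. Glucocorticoid targets were above (adjusted p = 0.0433), with Mt1 at 953 ± 130 TPM, a call that ended with the filtered background, with members in no other list and without library 1 (adjusted p = 0.0938, 0.108 and 0.0514). Interferon response (adjusted p = 0.631) and epithelial junction and keratin genes (adjusted p = 0.672, and 0.0358 with list means) did not differ from random lists, although Krt18 stood at 488 ± 75.8 TPM and Bst2 at 204 ± 23.8 TPM. In all, 12 lists were above and 6 below random lists, the 6 including the mitochondrial genome list, which held no counts.

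The cultures were also compared with each other. Parietal endoderm genes varied most, with a median SD of 0.688 on the log2 scale against 0.129 for matched lists (permutation, adjusted p = 0.000517). Col4a1 stood at 628, 2504, 853 and 2018 TPM in libraries 1 to 4, and Lama1, a laminin chain chosen after its values were seen, at 170, 733, 212 and 475 TPM. Secreted hepatocyte proteins (0.607), fibroblast genes (0.490), visceral endoderm genes (0.411), fetal liver genes (0.405) and pluripotency genes (0.319) had the same adjusted p. Cardiac (0.524), acute phase (0.459), endothelial (0.379), hepatic transcription factor (0.330), cholangiocyte (0.288), oxidative stress (0.271), glucocorticoid (0.266) and hypoxia (0.255) lists varied more as well. Of these, hepatic transcription factors were no longer called without library 1 or 4 (adjusted p = 0.0749 and 0.192), and cholangiocyte genes without 1 or 3 (0.0602 and 0.231). Endothelial genes were lost without 2 or 3 (0.592 and 0.219), hypoxia without 2 or 4 (0.230 and 0.0535), cardiac without 2 (0.444), and oxidative stress and glucocorticoid without 3 (0.778 and 0.121). Intestine genes, not called with all 4 libraries (0.0539), were called without 1, 2 or 4 (0.0411, 0.0358 and 0.0400). Coagulation and complement genes were called without 2 or 3 (0.0338 and 0.0288), p53 targets and primitive streak genes without 2 (0.0338 and 0.0456), and integrated stress genes without 4 (0.0400). In all, 14 of 31 lists varied more than matched lists, while lipid and cholesterol metabolism (0.0861) and nuclear oxidative phosphorylation (0.102) did not (adjusted p = 0.992 and 0.902). The 10 genes with the largest edgeR dispersion were Gapdh, Igfbp5, Fndc1, Enpep, Adamts9, Gkn2, Spock1, Fst, Ctla2a and Hsd11b2. Gapdh, a glycolytic enzyme, stood at 180, 18.5, 113 and 23.4 TPM, and Gkn2 at 53.7, 318, 67.1 and 153 TPM.

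**Figure D4:**
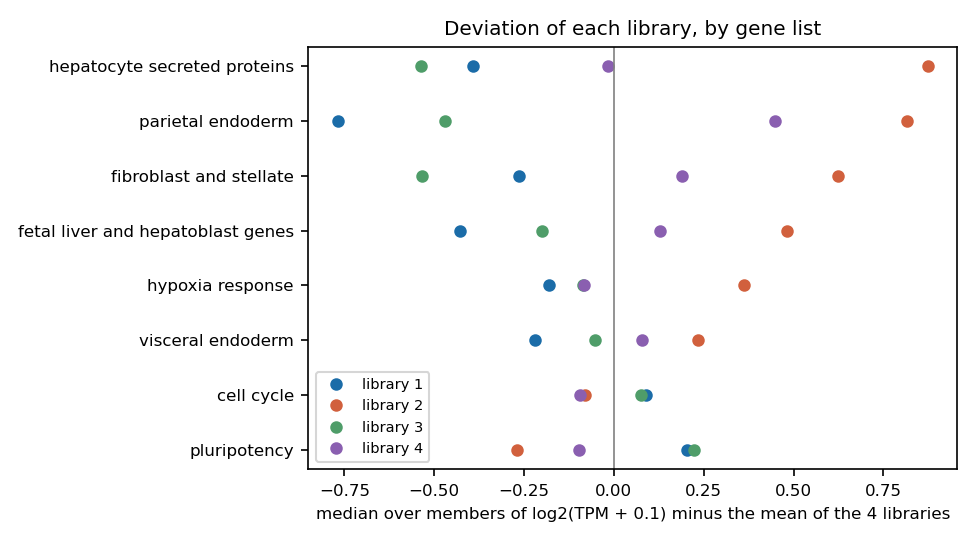
Median over list members of log2(TPM + 0.1) in each library minus the mean of the 4 libraries, for 8 gene lists. Library 2 is at 0.82 for parietal endoderm and at -0.27 for pluripotency.

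The common biological coefficient of variation was 0.205. Against the other 3, each of the 4 libraries had 0 genes past the threshold of 0.05 among 17398 tested (edgeR). At an unadjusted p under 0.05 there were 926, 1284, 274 and 269 genes for libraries 1 to 4, and DESeq2 called 8, 68, 3 and 3. With no filter on low counts edgeR called 328, 469, 1 and 6. The count became 2206 for library 1 without library 3, 2552 for library 2 without library 4, 1303 for library 3 without library 1 and 1386 for library 4 without library 2. In each of these the spread came from the 2 libraries left on the other side, which are close to each other, so the counts do not show that a single library differs. Differences between libraries were smallest for libraries 1 and 3 (root mean square 0.23 on the log2 scale) and libraries 2 and 4 (0.25), and lay between 0.33 and 0.46 for the other pairs. The main axis of variation (first principal component, 72.9% of the variance) also set libraries 1 and 3 apart from 2 and 4. Each library was thus compared with its close partner and the distant pair together, which widens the spread. The absence of edgeR calls therefore does not show that the libraries are alike. The labels give no batch or date that separates these cultures.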

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

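Of the tests of explanations in this part, only the one of library depth was chosen before its result was seen, and the others, with the look at phase I genes after thinning, were chosen after.

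In 18 of 182 sets of 4 values, 1 library lay far from the other 3. In 8 of these the other 3 values are equal, at 0 or at the pseudocount, which singles out the remaining one whatever its size. In 11 sets all 4 values are equal. Of the 163 other sets 10 were singled out, against about 8 by chance (1 in 20). Phase I drug metabolism (list median -2.93) and erythroid genes (-1.71) were highest in library 1, and epithelial genes (3.45) were lowest there. Oxidative stress genes were highest in library 3 (7.57), as was the log2 ratio of Gys2 to Gys1 (-8.03), which follows from Gys2. Library 2 had the highest Alb (7.18 TPM), Serpina1a (0.268 TPM), Apoc3 (0.194 TPM), Otc (0.0927 TPM) and Gys1 (58.8 TPM), and the lowest Pcx (29.5 TPM), Spp1 (560 TPM) and Gls2 (12.1 TPM). Fbp1 (1.87 TPM) and Cyp3a11 (0.0380 TPM) were highest in library 1, Gys2 (0.0955 TPM) in library 3, and Cebpa (8.80 TPM) and Cyp3a16 (0.222 TPM) in library 4.

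Pluripotency transcripts were high and hepatocyte transcripts low in the libraries labelled hepatocyte-like. Loss of reads to overlapping gene models of the GENCODE M21 annotation is argued against. Of the 41 secreted and mature genes below 1 TPM in at least 1 library, 2.44% (1 gene) share over 50% of their exon bases with another gene there. Only 48850 of the 78028 deposited rows were matched to that annotation. Overlap with the unmatched rows was not covered and stays open. Gene length is argued against too, since the pluripotency list stood 7.99 above the secreted proteins in log2 CPM (permutation over genes, adjusted p = 0.00014). Pou5f1, Nanog and Sox2 were all above 100 TPM in 4 of 4 libraries. A wrong label and undifferentiated cells left in the cultures cannot be told apart, because the series has no undifferentiated library, and no biological explanation was tested against a second group.

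Parietal endoderm genes differed between the libraries. After every library was thinned to the smallest total, the range of the list median in log2 TPM was 1.66, the same as before. By the reading set beforehand this argues against depth. Thinning shifted no library's median of these abundant genes by more than 0.00126, however, so the test had little room to come out otherwise. The range of phase I genes went from 0.40 to 0, but their median already lay at the pseudocount in libraries 2 to 4. That change shows only what thinning does near the floor. In log2 CPM the range was 1.33 with TMM scaling and 1.23 with total counts, which argues against scaling. Feeder fibroblasts with an intact Hprt1 gene cannot be told apart from other sources, since Hprt1 in library 2 was 0.362 times that in the other 3 (interval 0.111 to 0.922) on only 5 and 37 halved counts. A candidate explanation is that the mix of extraembryonic endoderm-like and pluripotent cells differs between cultures. In libraries 1 to 4, pluripotency genes below the mean of the other 3 numbered 3, 21, 1 and 19 of 23. Parietal endoderm genes above it numbered 0, 13, 1 and 14 of 14. Fibroblast (4, 19, 3 and 15 of 22), fetal liver (1, 18, 5 and 16 of 20), secreted hepatocyte (7, 16, 6 and 10 of 20) and hypoxia genes (4, 14, 3 and 2 of 14) were also above it most often in library 2. The cells that made these transcripts were not identified, so these lists do not decide for or against that mix. Which cells or states differ stays open.

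Gapdh differed between the libraries. Summed with its 5 named copies, which together held 33 to 59 counts per library, it still ranged 9.97-fold, against 10.5-fold for Gapdh alone in CPM. These values argue against reads moving to those 5 copies. Copies under other names, if any, were not summed. Other glycolysis genes, chosen after their values were seen, ranged from 1.07-fold (Pgam1) to 1.73-fold (Aldoa). Among 31 other genes with 5 or more pseudogene rows and a mean of 100 TPM or more, the largest range was 2.36-fold. That minimum leaves out genes that lost most of their reads, and Gapdh itself, at a mean of 83.8 TPM, lies under it. The check therefore covers well-counted genes only and cannot decide whether such genes lost reads together. Reads of Gapdh itself dropped for aligning to several places leave no count, so that source stays open, and no biological explanation was tested.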

How the results depend on the processing

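The alternatives with halved counts and the count of lineage lists above the secreted proteins were chosen only after the data were seen, and the others before. Of the values that answer a comparison, 87 were the same under an alternative and 22 moved. Of the list levels, lineage differences and pairs, 550 kept their direction and their side of the threshold, 26 passed it and 11 no longer did. In 9 the direction reversed, with neither value past the threshold: against random lists, urea cycle (-0.76), cholangiocyte (-0.67) and epithelial genes (-0.36) with the background of 10 or more counts, trophoblast (0.37), interferon (0.21) and line and sex genes (0.11) with list means, and the last with CPM (0.21); cardiac genes against secreted proteins with list means (-0.11); and Cyp3a11 to Cyp3a16 (-0.56 to 0.15 leaving out a library).

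With the background of genes with 10 or more counts, 20 lists in place of 6 were below random lists. That background has a higher median by construction, and the lists themselves were not filtered. With list means, 10 lists were below. Lineage lists below the secreted proteins went from 1 to 0 with CPM and to 0 with a pseudocount of 1, and leaving out a library gave 0 to 1. The secreted proteins' share was 0.00996% of summed TPM, against 0.00467% of counts. The biological coefficient of variation was 0.252 with no filter on low counts, 0.177 with halved counts, and 0.185 to 0.221 leaving out a library. Genes differing in libraries 1 to 4, 0 each by edgeR (926, 1284, 274 and 269 at an unadjusted p under 0.05), became 328, 469, 1 and 6 with no filter, and 8, 68, 3 and 3 by DESeq2. Leaving out a library gave 0 to 2206, 0 to 2552, 0 to 1303 and 0 to 1386, where for each highest count the 2 libraries left to give the spread are close to each other (root mean square 0.23 and 0.25 on the log2 scale). For the other changes, apart from the background, the cause was not tested.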
